A study of Mus musculus with 16 samples.

How the data were processed

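Gene expression was measured by RNA sequencing of mouse brain. Per the labels, total RNA was extracted with Qiazol, purified on columns and treated with DNase I, and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand of the RNA. The series holds 16 libraries in 4 groups of 4, given by diet and age in the labels. The letters that name the libraries differ between groups, so no library was paired with another.

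The authors deposited a table of raw read counts per gene, with 1 column per library and 48440 genes, of which 35022 had a count above 0 in at least 1 library. Per the submitters' processing notes, FastQC, Trimmomatic and STAR were used with the mouse genome build mm10. The counting program, its strand setting, the annotation and the tool versions are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be assigned with certainty. The same holds for genes with near-identical copies, such as C4b, the Serpina3 family, Lyz2, Ifit3, H2-K1, H2-D1 and the alpha globins. Gene symbols and coordinates were taken from the table, and starts were raised by 1 to count from 1. Of the 48440 identifiers, 48058 matched a GENCODE annotation of the same build, all on the same chromosome, and 90.5% of these had the same start after that step. Symbols that occur for more than 1 gene were kept apart by their identifiers. The mitochondrial genes mt-Co2, mt-Atp8 and mt-Nd4l are listed at 0 in all 16 libraries, and mt-Atp6 and mt-Co3 reach at most 1 count, while mt-Co1 has 48136 to 105819. These 5 genes and mt-Nd3, with at most 8 counts, were not tested.

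Total counts per library ran from 10348163 to 15642116. Within groups, 24 pairs of libraries were compared by a chi-square test of their counts, and the statistic per degree of freedom lay between 4.44 and 192, so no pair agreed within sampling noise, as 1 library deposited more than once would. This test does not tell separate mice from repeated preparations of 1 mouse. Each library was used as 1 replicate because the labels list it as a sample of its own. All libraries had between 549 and 1079 counts of the Y-linked gene Ddx3y and at most 18 of Xist, the marker of the inactive X chromosome.

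Differences between groups were tested on the counts with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's default expression filter for the 4 groups, which left 17762, library sizes were scaled by the TMM method, and 1 quasi-likelihood model with a mean per group was fitted to all 16 libraries with robust dispersion estimates. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. A fold change is the ratio of group means on the log2 scale, and its standard error (SE) is the absolute log2 change divided by the square root of the F statistic. Levels are CPM, the counts scaled by library size and TMM factor, as mean ± SD over 4 libraries. The comparisons were 26 against 13 months in each diet, ketogenic against control diet at each age and averaged over the ages, and the interaction of diet and age.

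Before the data were examined, 48 gene lists of brain cell types, brain regions, metabolic pathways and stress and immune responses were fixed, of which 47 had at least 4 tested members. The list of lymphocyte genes had fewer. Lists were tested against all other genes with limma 3.58.1 camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and adjustment over the 47 lists in each comparison. Camera with a correlation estimated from the residuals, and fry, which asks whether a list's genes move on balance in 1 direction, served as alternatives. For each list, the number of members called over all genes tested and the number called when adjusted over the list alone were counted. The score of a list in a library is the mean of its members' log2 CPM, centred per gene, and differences of scores between groups were tested by exact two-sided permutation, for which 4 against 4 libraries give a smallest p of 0.0286.

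The genes named were chosen by a rule fixed before the data were examined. It takes, per comparison, up to 8 higher and 8 lower genes with the smallest adjusted p, without unnamed gene models, or the 5 smallest p where fewer than 5 genes passed. It adds up to 4 called members of each list, or 2 members as values where a called list had none, and 14 genes in every case, from Gfap and C4b to the ketone body enzymes Bdh1 and Oxct1, of which 1 is not reported here. Genes outside the rule are marked as chosen after their values were seen.

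Across genes, the log2 changes of 2 comparisons were correlated by Pearson's r, with a two-sided exact p from all 4900 regroupings of the libraries within the compared pairs of groups. For the age change in controls and the diet change at 26 months, which share the 26-month control libraries, r was also computed with those 4 libraries split 2 and 2, with 70 regroupings, and set beside 20 simulated data sets without any group effect that keep the libraries' own structure. Genes are not independent replicates, so r describes the libraries and p refers to their regrouping.

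After the libraries had been seen, a model term for 4 libraries with little 18S rRNA, 1 in each group, was added as an alternative, and the model was fitted without these 4 libraries. Lists called with an estimated correlation were also retested with it and each library left out. The alternatives fixed before were DESeq2 1.42.0 and limma-voom tests, DESeq2 size factors and upper-quartile scaling, other filters, a fit to the compared groups alone, removal of mitochondrial genes, 1 surrogate variable from sva 3.50.0, a test against a fold of 1.2, and leaving out each library. DESeq2 gives no adjusted p for 364 of the tested genes for age in controls, 4145 for age under the ketogenic diet and 19 in each of the other comparisons.

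The steps were tested on simulated counts with the means, library sizes and spread of these libraries and 200 genes changed, of which those passing the filter are counted here. For the age effect in controls, the test recovered 43 of 98 genes changed 1.5-fold and 68 of 99 changed 2-fold, with 0 unchanged genes called. For the diet effect at 26 months it recovered 43 of 98 and 66 of 100, and for the interaction 27 of 98 and 56 of 100, again with 0 unchanged genes called. With the term for low 18S rRNA, the diet effect at 26 months gave 56 of 98 and 78 of 100, with 9 unchanged genes called. In a separate simulation with the list of glycolysis genes raised 1.25-fold under the diet at 26 months, camera with the preset correlation called that list and 1 other of 47. All simulated genes were drawn independently, so this does not test the preset correlation on genes that vary together. Regrouped real libraries, described below, gave up to 26 called lists in that comparison.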

Results

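Mice were assigned at random to a control diet or a ketogenic diet, which is rich in fat and very low in carbohydrate, at 12 months of age, and brains were collected at 13 and 26 months, after 1 and 14 months on the diet. The title of the series names its purpose, the effect of this diet on brain gene expression that changes with ageing. The 16 RNA-seq libraries fall into 4 groups of 4, control libraries A, B, C and E and ketogenic libraries F, G, H and J at 13 months, and control libraries K, L, M and N and ketogenic libraries O, P, Q and R at 26 months. Each held 10348163 to 15642116 counts. The labels do not say whether every library came from a different mouse, so the p-values measure the spread between these libraries, which may be partly technical. Coordinates are those of mm10.

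A library's 18S rRNA share set 4 libraries apart, 1 in each group. In C, J, K and R this share was 0.0372 to 0.425% of counts, against 2.44 to 8.71% in the other 12. These 4 had a mean of 1.18 ± 0.0723% of counts (SD, n = 4) on Malat1, a long RNA retained in the nucleus, against 0.565 ± 0.0705% (SD, n = 12), and 27299 to 28157 detected genes against 24477 to 26382. The first principal component, with 41.7% of the variance, separated them from the rest, and the next component held 8.20%. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3566 genes were higher and 3262 lower in these libraries, referred to here as low-18S libraries. Each group held 1 of them. Library G of the 13-month ketogenic group held liver transcripts, with 1912 counts of albumin (Alb) against at most 12 in the rest of its group, and library P of the 26-month ketogenic group held neutrophil transcripts, with 161 counts of S100a9 against at most 18.

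**Figure D1:**
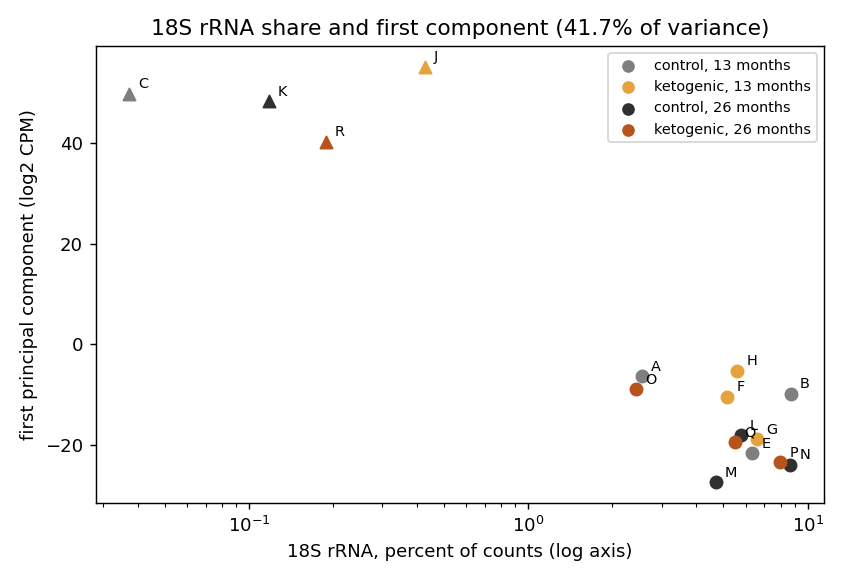
Each point is 1 of the 16 libraries, coloured by group, with its 18S rRNA share in percent of counts on a log axis and its position on the first principal component of log2 CPM (41.7% of the variance). The 4 low-18S libraries (triangles, shares of 0.0372 to 0.425%) lie between 40.3 and 55.2 on this component, and the other 12 between −27.5 and −5.24.

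The comparison of 26 with 13 months in control-fed mice asked which brain genes change with age on the control diet. Genes of microglia, complement, the interferon response and reactive astrocytes rose. C4b, which encodes complement component 4, had the smallest adjusted p (ENSMUSG00000073418.4, chromosome 17, 34728380 to 34743882). It rose 3.14-fold, from 32.9 ± 1.91 to 103 ± 11.9 CPM (SD, n = 4 per group), a log2 change of 1.65 ± 0.12 (SE, adjusted p = 1.73e-06). Gfap, the intermediate filament of astrocytes (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912), rose 2.03-fold, from 122 ± 16.9 to 248 ± 38.4 CPM (adjusted p = 0.00402). Serpina3n, a protease inhibitor of reactive astrocytes (ENSMUSG00000021091.8, chromosome 12, 104406729 to 104414329), rose 2.22-fold, from 8.88 ± 0.651 to 19.6 ± 3.37 CPM (adjusted p = 0.00738).

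In all, 33 genes rose and 4 fell of 17762 tested. Among the other genes with the smallest adjusted p were Lyz2, lysozyme of myeloid cells (log2 1.42 ± 0.21 SE), Mpeg1, a pore-forming protein of macrophages (0.82 ± 0.11), Ctss, the lysosomal protease cathepsin S (0.62 ± 0.10), Lgals3bp, a secreted galectin-binding protein (0.88 ± 0.14), and Dbp, a clock-controlled transcription factor (0.64 ± 0.10). The 4 that fell were Gng4, a G protein subunit (−0.64 ± 0.10), Pbx3, a homeobox factor of olfactory bulb interneurons (−0.66 ± 0.11), Lgr6, a receptor for R-spondins (−0.97 ± 0.17), and Rab37, a small GTPase (−0.61 ± 0.11). Gng4 is also in the set of bulb interneuron markers weighed below, which was chosen after the results were seen. Of the genes named in every comparison, Clec7a, a receptor of activated microglia, rose (2.59 ± 0.44), from 2 to 9 counts per library at 13 months to 24 to 34 at 26 months. Cst7, a cysteine protease inhibitor of the same microglial state, did not pass (1.40 ± 0.49, adjusted p = 0.559). Neither did Bdh1 (0.06 ± 0.08), Oxct1 (−0.05 ± 0.05), Slc16a1 (−0.06 ± 0.10), Pdk4 (0.19 ± 0.20), Cpt1a (−0.04 ± 0.13), Fkbp5 (0.34 ± 0.22), Nlrp3 (0.10 ± 0.35) or Bdnf (−0.03 ± 0.11). C4b, the Serpina3 family, Lyz2, Ifit3, H2-K1 and H2-D1 have near-identical copies, so their counts may include reads of those copies. The ketone body list (9 genes, median −0.01, adjusted p = 0.578) and the PPAR target list (29 genes, median −0.02 and mean 0.00, adjusted p = 0.958) were not called.

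Of 23 tested genes of the disease-associated microglia list, 6 rose and 18 did so when adjusted over the list alone, with a median log2 change of 0.62. They included Trem2, a lipid receptor of microglia (0.71 ± 0.14). Of 12 complement genes, 3 rose (8 when adjusted over the list alone, median 0.63), among them C1qa (0.75 ± 0.13) and C1qc (0.86 ± 0.16), chains of the C1q initiator. Of 25 interferon response genes, 6 rose (19 when adjusted over the list alone, median 0.81) and all 25 had a positive log2 change. Ifit1 (1.45 ± 0.27) and Ifit3 (1.09 ± 0.19), which block viral RNA, and Ifitm3 (1.17 ± 0.21), which blocks viral entry, were among them. Of 17 antigen presentation genes, 3 rose (12 when adjusted over the list alone, median 0.76), namely Tap1, the peptide transporter (1.16 ± 0.23), B2m (0.76 ± 0.12) and H2-K1 (0.87 ± 0.16), parts of MHC class I. Of 21 reactive astrocyte genes, 3 rose (15 when adjusted over the list alone, median 0.52), Gfap, Serpina3n and Osmr, the oncostatin M receptor (0.74 ± 0.15). Of 11 inflammasome and cytokine genes, Tlr2, a pattern recognition receptor, rose (1.74 ± 0.30; 3 genes when adjusted over the list alone, median 0.23). With an estimated correlation, the adjusted p of these 6 lists was 0.00391 for reactive astrocytes, 0.0496 for the inflammasome list and 0.00483 for the other 4, and with a term for the low-18S libraries as well it was 0.0789 for the inflammasome list.

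Markers of the olfactory bulb, the brain's first station for smell, fell together. None of the 10 tested genes had a positive log2 change, 1 fell over all genes (Pbx3), 9 fell when adjusted over the list alone, and the median was −0.77 (adjusted p = 0.00483 with an estimated correlation). These 7 lists kept the preset call with each library left out. With an estimated correlation as well, 6 of them kept it, and the inflammasome list lost it without A (adjusted p = 0.0758), B (0.0613), C (0.123), E (0.089), K (0.0968), L (0.0659) or M (0.0663). Of 18 circadian clock genes, Dbp and Ciart, a repressor of the clock (0.85 ± 0.17), rose. When adjusted over the list alone, 8 rose and 2 fell, and the call of the list was lost with an estimated correlation (adjusted p = 0.0601). Arntl, which encodes the clock activator BMAL1 and was chosen after its values were seen, had −0.53 (adjusted p = 0.0632). The labels used here give no hour or date of collection. Under either diet, changes of clock genes with age can therefore not be told apart from a difference in collection. The same holds for all other changes with age reported here. Time on the diet also rose with age and cannot be told apart from it. Another 11 lists were called with the preset correlation and not with an estimated one, none of them with a member called over all genes. The adjusted p with an estimated correlation was 0.0714 for homeostatic microglia (6 of 14 higher when adjusted over the list alone), 0.421 for cholesterol synthesis, 0.14 for pericytes and smooth muscle, 0.321 for the cerebellum list, whose median was −0.32, and 0.327 for neuropeptides. It was 0.421 for cortex and hippocampus, 0.563 for NRF2 targets, 0.64 for excitatory neurons, choroid plexus (median −0.39) and meningeal fibroblasts, and 0.683 for glucocorticoid-responsive genes. Medians were positive in all but the cerebellum and choroid plexus lists. Of the 12 lists lost with an estimated correlation, 7 also lost the preset call when 1 library was left out. Without C these were the excitatory (adjusted p = 0.813), meningeal (0.443), glucocorticoid (0.294), cortex (0.183), neuropeptide (0.125) and NRF2 lists (0.0747). The glucocorticoid list also lost it without A (0.0679) or K (0.0525), choroid plexus without B (0.0951), E (0.091) or K (0.242), the excitatory list without M (0.0963) or N (0.121), the meningeal list without L (0.16) or M (0.0865) and neuropeptides without L (0.0699) or N (0.0856).

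The 37 calls were all among the 143 genes (105 higher, 38 lower) found with a term for the low-18S libraries, and 34 were among the 108 found without these libraries, while DESeq2 called 81, 1 surrogate variable gave 135, the compared groups alone 15 and a test against a fold of 1.2 gave 6. Without B, 36 genes were called, 18 higher and 18 lower, of which 18 are among the 37, and without K 42 (35 higher, 7 lower), of which 30 are. Without L, 8 genes were called, without A 14, without C 17, and without E, M or N 22 each, and with the low-18S term 93 without C and 81 without L. C4b, Gfap, Serpina3n, Mpeg1, Dbp, Lyz2 and Gng4 kept their calls with each library left out. The other 18 named genes that passed lost the call without at least 1 library. The largest adjusted p was that without L for Osmr (0.24), Trem2 (0.216), Ifit1 (0.162), Tap1 (0.144), C1qc (0.133), Ifitm3 (0.117), C1qa, Ifit3 and Tlr2 (0.113), Clec7a and Lgr6 (0.0745) and Ctss, Lgals3bp and Pbx3 (0.0743). It was that without A for H2-K1 (0.174), without E for Ciart (0.161) and without C for Rab37 (0.108) and B2m (0.0595).

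**Figure D2:**
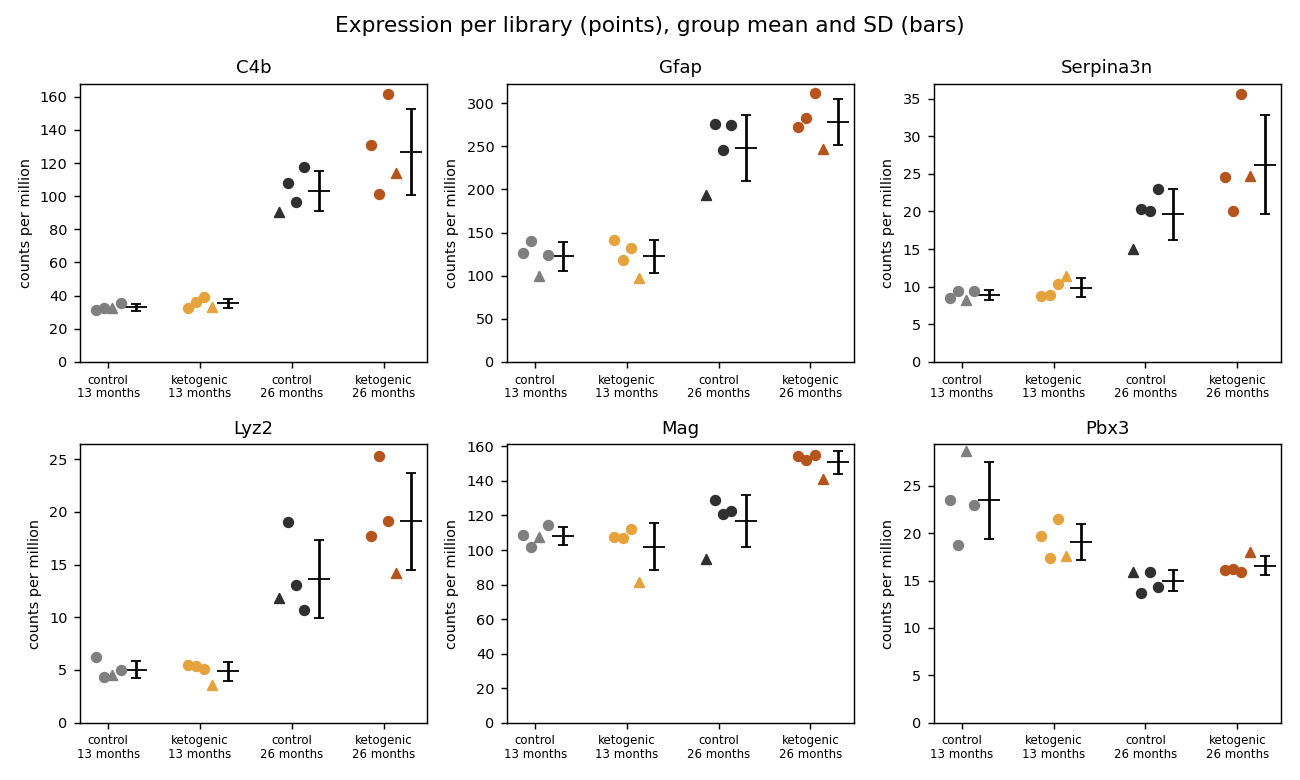
Levels of 6 genes in CPM in the 16 libraries (points; triangles are the low-18S libraries) of the 4 groups, with the mean and SD of each group of 4 as bars. C4b is at 31.1 to 39.0 CPM in every 13-month library and at 90.7 to 161 in every 26-month library, and Mag is at 141 to 155 in ketogenic libraries at 26 months against 95.1 to 129 in control libraries of that age.

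The same comparison in ketogenic-fed mice asked which genes change with age between 1 and 14 months on the ketogenic diet. Microglial, complement, antigen presentation and astrocyte genes rose here too, and 2 myelin genes rose. C4b rose 3.60-fold, from 35.3 ± 2.90 to 127 ± 26.0 CPM (SD, n = 4 per group; log2 1.85 ± 0.12 SE, adjusted p = 2.57e-07). Gfap rose 2.28-fold, from 122 ± 18.99 to 278 ± 27.0 CPM (adjusted p = 2.62e-04), and Serpina3n 2.67-fold, from 9.86 ± 1.24 to 26.2 ± 6.62 CPM (adjusted p = 2.13e-04). Mag, the myelin-associated glycoprotein (ENSMUSG00000036634.15, chromosome 7, 30899176 to 30914873), rose 1.48-fold, from 102 ± 13.7 to 151 ± 6.69 CPM (adjusted p = 0.00944).

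Here 35 genes rose and 4 fell of 17762. Lyz2 (log2 1.97 ± 0.21 SE), Dbp (0.92 ± 0.10), Ctss (0.88 ± 0.10), Mpeg1 (0.88 ± 0.11) and Cd84, an adhesion receptor of immune cells (1.18 ± 0.14), had the smallest adjusted p after C4b, Gfap and Serpina3n. The 4 that fell were Gng4 (−0.51 ± 0.10), Fgf12, a modulator of sodium channels (−0.34 ± 0.07), Plppr5, a lipid phosphatase-related protein of neurons (−0.46 ± 0.09), and Raph1, a regulator of actin (−0.33 ± 0.07). Clec7a rose (2.28 ± 0.40), while Cst7 (1.02 ± 0.47, adjusted p = 0.418) did not pass. The values were 0.13 ± 0.08 for Bdh1, −0.01 ± 0.05 for Oxct1, −0.02 ± 0.10 for Slc16a1, 0.13 ± 0.20 for Pdk4, −0.06 ± 0.13 for Cpt1a, 0.11 ± 0.22 for Fkbp5, −0.04 ± 0.36 for Nlrp3 and −0.21 ± 0.11 for Bdnf, none of which passed. The ketone body list (median −0.01 and mean 0.02, adjusted p = 0.857) and the PPAR target list (median 0.04, adjusted p = 0.257) were not called.

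Of 23 disease-associated microglia genes, 8 rose and 20 did so when adjusted over the list alone (median 0.60, adjusted p = 0.0135 with an estimated correlation). Among them were Trem2 (0.94 ± 0.14) and Itgax, the integrin CD11c (3.03 ± 0.45). Of 12 complement genes, 5 rose, and the same number when adjusted over the list alone (median 0.49, adjusted p = 0.0154 with an estimated correlation), including C1qa (0.88 ± 0.13), C1qb (0.70 ± 0.13) and Itgb2, a chain of the complement receptors (1.27 ± 0.19). Of 17 antigen presentation genes, H2-D1, an MHC class I chain, rose (0.59 ± 0.12), and 13 rose when adjusted over the list alone (median 0.74, adjusted p = 0.02 with an estimated correlation). Of 21 reactive astrocyte genes, Gfap, Serpina3n and Vim, another intermediate filament (0.64 ± 0.12), rose, and 11 rose when adjusted over the list alone (median 0.54, adjusted p = 0.0135 with an estimated correlation). These 4 lists kept the preset call with each library left out, and with an estimated correlation as well 3 of them did, while antigen presentation lost it without J (adjusted p = 0.0584).

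Of 17 myelin genes, Mag (0.56 ± 0.09) and Mog, a glycoprotein of the outer myelin surface (0.51 ± 0.09), rose, and 11 rose when adjusted over the list alone (median 0.35). The list was not called with an estimated correlation (adjusted p = 0.22), and was called in that test with a term for the low-18S libraries (adjusted p = 0.0457). Of 25 interferon response genes, Lgals3bp rose (0.88 ± 0.14), and 16 rose when adjusted over the list alone (median 0.60, adjusted p = 0.0824 with an estimated correlation). All 7 tested mitochondrial mRNAs had a negative log2 change, with a median of −0.54, and 6 fell when adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). The adjusted p with an estimated correlation was also 0.22 for the olfactory bulb list (median −0.47, 2 of 10 lower when adjusted over the list alone) and 0.279 for the 7 blood cell genes (median 1.71), whose score was 2.35 in P, the library with neutrophil transcripts, and 1.91 in Q, against at most 0.285 in O and R. Dbp was the 1 circadian gene called over all genes, and the list's adjusted p with an estimated correlation was 0.447. A further 13 lists were called with the preset correlation and without a member called over all genes. Their adjusted p with an estimated correlation was 0.34 for inflammasome and cytokines, 0.407 for homeostatic microglia, 0.439 for inhibitory neurons and for pericytes, 0.447 for cholesterol synthesis and for synaptic genes, and 0.598 for glycolysis. It was 0.757 for immediate early genes, excitatory neurons, choroid plexus, NRF2 targets and ribosomal proteins and 0.792 for nuclear-encoded oxidative phosphorylation. Of the 19 lists lost with an estimated correlation, 11 also lost the call when 1 library was left out, and the oxidative phosphorylation list changed direction without J (adjusted p = 0.41). Medians were negative for immediate early, inhibitory, excitatory, synaptic and choroid plexus genes and positive in the other 8 of these 13 lists. Without J the ribosomal (0.694), NRF2 (0.339), circadian (0.208), cholesterol (0.103) and inflammasome lists (0.0872) lost the preset call. Without F it was lost by the immediate early (0.193), excitatory (0.132) and inflammasome lists (0.114), without G by excitatory (0.0885) and choroid plexus genes (0.0875), and without H by choroid plexus genes (0.332). Without O it was lost by oxidative phosphorylation (0.27), inflammasome (0.14), NRF2 (0.0558) and pericyte genes (0.0535) and without P by oxidative phosphorylation (0.342). Without Q it was lost by circadian (0.249), inflammasome (0.0908) and NRF2 genes (0.0773), and without R by immediate early (0.361), excitatory (0.178), pericyte (0.129) and inhibitory neuron genes (0.101).

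All 39 calls were among the 675 genes (406 higher, 269 lower) found with a term for the low-18S libraries and among the 547 found without these libraries, while a test against a fold of 1.2 gave 15 and 1 surrogate variable 636. DESeq2 called 160, which hold 34 of the 39, and gave no adjusted p for Itgax and Clec7a. The compared groups alone gave 43 (30 higher, 13 lower), which hold 25 of the 39. Without P, 16 genes were called, without F or Q 19, without J 21, without G or O 25, and without R 74, with 0 lower without F, H, O or P, 1 without G, J or Q and 11 without R, and with the low-18S term 304 without F, 325 without H, 388 without O, 312 without P and 444 without Q. C4b, Gfap, Serpina3n, Lyz2, Mpeg1, Dbp, Ctss, Cd84, Trem2, Itgax, Itgb2, C1qa and Lgals3bp kept their calls with each library left out. Mag lost its call without P (adjusted p = 0.0573) or Q (0.0648), and Mog without F (0.0785), P (0.0675) or Q (0.077). The other 8 named genes that passed lost it without at least 1 library. The largest adjusted p was that without P for Raph1 (0.201) and Plppr5 (0.153), without F for Clec7a (0.0954), and without Q for H2-D1 (0.2), Fgf12 and Gng4 (0.194), Vim (0.184) and C1qb (0.172).

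Whether age moved the same genes under both diets was examined by overlap and by correlation, in comparisons that share no library. C4b, Gfap, Serpina3n, Lyz2, Clec7a, Trem2, C1qa, Dbp and Gng4 were among the 17 genes called in both diets, all 17 in the same direction. Independent lists would share 0.065 genes that rose and 9.01e-04 that fell, if every tested gene were equally likely to be called. Both comparisons come from 1 model, and genes with little spread pass more readily in both. These chance figures may therefore be too low. All 37 genes called in controls had the same sign under the ketogenic diet, and 37 of the 39 called under the ketogenic diet had the same sign in controls. With the low-18S term, 138 of the 143 genes called in controls and 508 of the 675 called under the ketogenic diet had the same sign in the other diet. Of these, 76 were called in both, all in the same direction, where independent lists would share 2.40 that rose and 0.575 that fell, with the same limit. Across all 17762 genes, the log2 changes of the 2 diets had a Pearson r of 0.341, which did not differ from that of regrouped libraries (exact permutation p = 0.186 over 4900 regroupings), and over the 37 genes called in controls r was 0.874. With the low-18S term removed from the values, r over all genes is the same by construction and the exact permutation p was 0.0049. Genes are not independent replicates, and r describes these libraries.

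The comparison of diets at 13 months asked what 1 month of ketogenic feeding changes. The ketone-using enzymes Bdh1 (−0.01 ± 0.08) and Oxct1 (−0.04 ± 0.05), and Slc16a1, the monocarboxylate transporter of the blood-brain barrier (0.04 ± 0.10), did not pass the test (log2 ± SE, n = 4 per group, adjusted p = 1). The list of 9 tested ketone body genes was not called (median −0.04, adjusted p = 0.739), nor was that of 29 PPAR target and fatty acid oxidation genes (median 0.01, adjusted p = 0.743), which holds Pdk4, an inhibitor of glucose oxidation (0.07 ± 0.20), and Cpt1a, the carnitine transferase of fatty acid import (0.11 ± 0.13).

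No gene of 17762 was called at 13 months by edgeR, DESeq2 or limma-voom, and by edgeR 357 had an unadjusted p below 0.05, where 888 are expected by chance. Such a shortfall can mean that the fit is conservative, so 0 calls do not show that the diet has no effect. The 5 smallest p belonged to Mical2, an actin-oxidising enzyme (0.23 ± 0.06), Dcn, the matrix proteoglycan decorin (0.58 ± 0.15), Rab37 (−0.39 ± 0.11), Tut1, an RNA uridylyltransferase (0.26 ± 0.08), and Qprt, an enzyme of NAD synthesis (1.53 ± 0.44), none passing (adjusted p = 1). C4b (0.10 ± 0.12), Gfap (0.00 ± 0.13), Serpina3n (0.16 ± 0.17), Clec7a (0.79 ± 0.50), Cst7 (0.52 ± 0.53), Fkbp5 (0.05 ± 0.23), Nlrp3 (−0.05 ± 0.36) and Bdnf (0.19 ± 0.11) did not pass either. DESeq2 gave 245 genes and limma-voom 371 at an unadjusted p below 0.05. With a term for the low-18S libraries, chosen after seeing the data, edgeR gave 813 and called 0.

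Camera with the preset correlation called 9 lists, and none was called with an estimated correlation (adjusted p = 0.957 for each) or by fry. Thalamus markers had a median of −0.30, with 10 of 11 negative, and 3 fell when adjusted over the list alone. The 7 mitochondrial mRNAs had a median of 0.31 and the 14 meningeal fibroblast genes, which include Dcn, a median of 0.22, all positive, with 1 higher when adjusted over the list alone. The medians were 0.10 for excitatory neurons, 0.05 for synaptic genes, 0.17 for immediate early genes and 0.11 for cortex and hippocampus, and −0.06 for ribosomal proteins and −0.03 for oxidative phosphorylation. The preset calls of thalamus markers and mitochondrial mRNAs held with each library left out. Without C the meningeal (adjusted p = 0.246), synaptic (0.522), excitatory (0.937), cortex (0.768) and immediate early (0.652) lists lost the call, and without J the ribosomal (0.245) and oxidative phosphorylation (0.113) lists did so and changed direction. The excitatory list also lost it without F (0.136) or G (0.0606), the cortex list without F (0.153), the immediate early list without B (0.678), F (0.823), G (0.216) or H (0.284), and the ribosomal (0.513 and 0.196) and oxidative phosphorylation lists (0.966 and 0.361) without B or E.

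The comparison of diets at 26 months asked what 14 months of ketogenic feeding change. No myelin gene passed the test over all genes, and the myelin list was called higher under the ketogenic diet with the preset correlation, but not with an estimated one (adjusted p = 0.849) or by fry (adjusted p = 0.855). Mag had 151 ± 6.69 CPM under the ketogenic and 117 ± 15.0 under the control diet (SD, n = 4 per group; log2 0.37 ± 0.09 SE, adjusted p = 0.857), and Mog had a log2 difference of 0.34 ± 0.09. All 17 tested myelin genes had a positive log2 difference, with a median of 0.20. The ketone body list was not called (median 0.05, adjusted p = 0.725), with Bdh1 at 0.06 ± 0.08, Oxct1 at −0.01 ± 0.05 and Slc16a1 at 0.08 ± 0.10. The PPAR target list was not called (median 0.07, adjusted p = 0.11), with Pdk4 at 0.01 ± 0.20 and Cpt1a at 0.09 ± 0.13.

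No gene of 17762 was called by edgeR, and 953 had an unadjusted p below 0.05 where 888 are expected. The 5 smallest p belonged to Lrch2, a leucine-rich repeat protein (−0.40 ± 0.08), Lgi3, a secreted leucine-rich repeat protein (0.26 ± 0.05), Pqlc1 (0.48 ± 0.11), Llgl1, a cell polarity protein (0.30 ± 0.07), and Chadl, a chondroadherin-like matrix protein (0.53 ± 0.12), all with an adjusted p of 0.857. The age-related genes C4b (0.30 ± 0.11), Serpina3n (0.43 ± 0.15), Gfap (0.17 ± 0.13), Clec7a (0.48 ± 0.34) and Cst7 (0.14 ± 0.43) did not pass, nor did Fkbp5 (−0.19 ± 0.22), Nlrp3 (−0.20 ± 0.35) or Bdnf (0.02 ± 0.11). DESeq2 called 1 gene, Lgi3, with 809 at an unadjusted p below 0.05, and limma-voom 0, with 969. With a term for the low-18S libraries, chosen after seeing the data, edgeR gave 1814 genes at an unadjusted p below 0.05 and called 14 genes. Of those named here, Cnp, Olig1, S100b, Fgf12 and mt-Tp were chosen after their values were seen. Mag (0.38 ± 0.06), Mog (0.34 ± 0.07), Cnp, an enzyme of myelin (0.31 ± 0.06), Olig1, a transcription factor of oligodendrocytes (0.35 ± 0.06), and S100b, a calcium-binding protein of glia (0.35 ± 0.06), were among the 9 that rose, and the 5 that fell included Lrch2, Fgf12 (−0.26 ± 0.05) and mt-Tp, a mitochondrial tRNA (−0.50 ± 0.10). This count was 2 without K, 3 without M or O, 5 without L or Q, 8 without P, 28 without R and 69 without N. Without the 4 low-18S libraries 58 genes (21 higher, 37 lower) were called, and with 1 surrogate variable 31.

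Camera with the preset correlation called 7 lists, and none was called with an estimated correlation (adjusted p = 0.849 for each) or by fry. Myelin genes were higher (2 of 17 when adjusted over the list alone), as were the 7 blood cell genes (median 1.23, 1 when adjusted over the list alone), whose score was 2.35 in P, with its neutrophil transcripts, and 1.91 in Q, which had 8111 counts of the globin gene Hbb-bs, against at most 0.532 in the other 26-month libraries. The 25 interferon response genes were lower (median −0.28), with Ifi44 at −1.07 ± 0.39 and Parp14 at −0.56 ± 0.20. The 7 mitochondrial mRNAs were lower (median −0.38, 2 when adjusted over the list alone), with mt-Co1, a subunit of cytochrome c oxidase, at −0.38 ± 0.11. These 4 preset calls held with each library left out, while the interferon list lost its call without the 4 low-18S libraries (adjusted p = 0.359). The 23 disease-associated microglia genes had a median of 0.16, with 22 positive, and lost the call without K (adjusted p = 0.151). Cerebellum markers had a median of 0.17 and lost the call without M (adjusted p = 0.0722) or P (0.104), and excitatory neuron genes had a median of −0.10 and lost it without M (0.0769), N (0.156) or R (0.124).

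**Figure D3:**
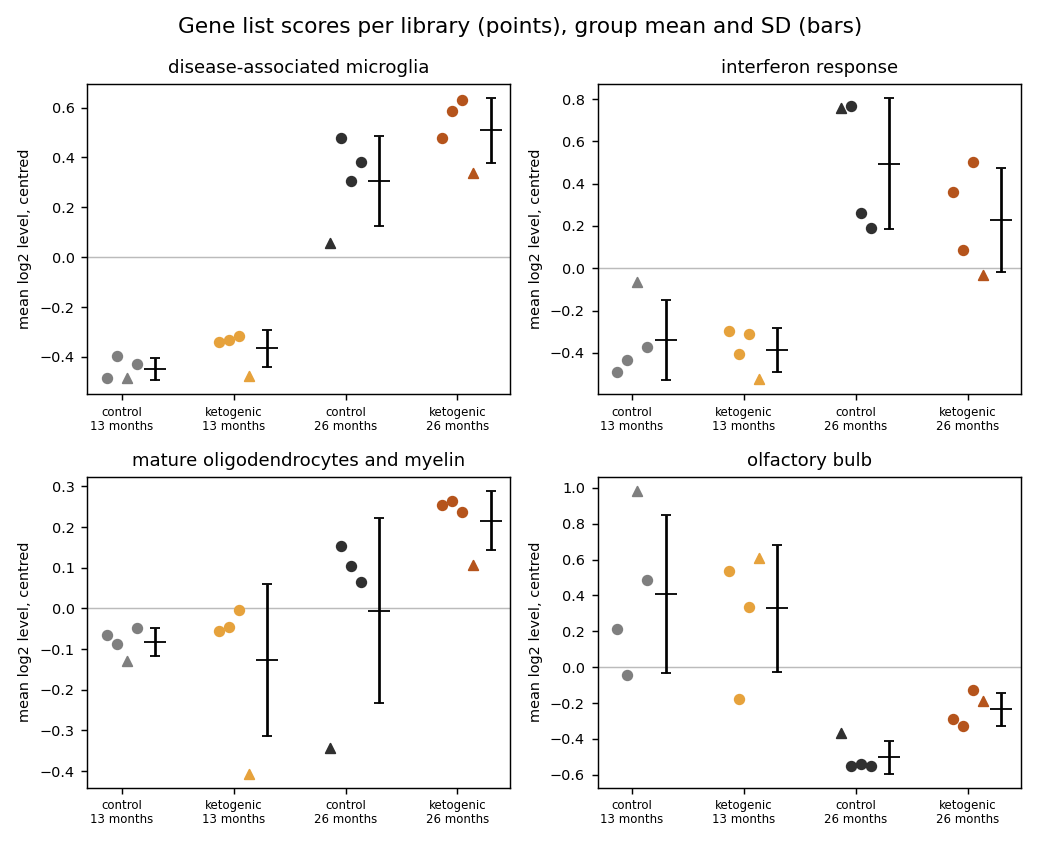
Scores of 4 gene lists in the 16 libraries (points; triangles are the low-18S libraries), as the mean log2 CPM of the members centred per gene, with the mean and SD of each group of 4 as bars. Myelin scores at 26 months are 0.237 to 0.263 in ketogenic libraries other than R (0.107), and 0.064 to 0.153 in control libraries other than K (−0.343), while microglia scores are above 0 in every 26-month library and below 0 in every 13-month library.

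Averaged over both ages, the diet effect was tested with all 16 libraries. Thalamus markers were lower and microglia, myelin, blood cell and cholesterol synthesis genes higher under the ketogenic diet with the preset correlation, with medians of −0.20, 0.10, 0.09, 0.53 and 0.03, and interferon response genes were lower (median −0.14). None of these 6 lists was called with an estimated correlation (adjusted p = 0.949 for thalamus, microglia, interferon and blood cells and 0.99 for myelin and cholesterol) or by fry. Of their members, 1 blood cell gene was higher and 1 thalamus gene lower when adjusted over the list alone. The ketone body list was not called (adjusted p = 0.959; its median was −0.00 and its mean 0.04).

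No gene of 17762 was called for the averaged diet effect by edgeR, DESeq2 or limma-voom, with 489, 364 and 494 genes at an unadjusted p below 0.05. About 888 are expected by chance, so here too 0 calls do not show that there is no effect. The 5 smallest p belonged to Glra3, a glycine receptor subunit (−0.37 ± 0.09), D3Ertd254e (−0.22 ± 0.05), Eif3e, a translation initiation factor (−0.16 ± 0.04), Mrps33, a mitochondrial ribosomal protein (−0.32 ± 0.09), and Mbip (−0.23 ± 0.06), all with an adjusted p of 1. C4b (0.20 ± 0.08), Serpina3n (0.29 ± 0.11), Gfap (0.08 ± 0.09), Clec7a (0.63 ± 0.30), Cst7 (0.33 ± 0.34), Bdh1 (0.02 ± 0.06), Oxct1 (−0.02 ± 0.04), Slc16a1 (0.06 ± 0.07), Pdk4 (0.04 ± 0.14), Cpt1a (0.10 ± 0.09), Fkbp5 (−0.07 ± 0.16), Nlrp3 (−0.12 ± 0.25) and Bdnf (0.10 ± 0.08) did not pass. Without K the microglia (adjusted p = 0.175), myelin (0.489) and cholesterol lists (0.195) lost the call, as did myelin without H (0.0671) and cholesterol without B, C, F, G, L, O or Q (0.0942 to 0.256). The interferon list lost it without the 4 low-18S libraries (0.998). With a term for these libraries, edgeR gave 1052 genes at an unadjusted p below 0.05 and called 0.

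The interaction asked whether the diet effect differs between the ages, which is also whether the age effect differs between the diets. Age and time on the diet rose together, so the interaction cannot tell them apart. Camera with the preset correlation called 12 lists, and none was called with an estimated correlation (adjusted p = 0.883 for each) or by fry. The 7 mitochondrial mRNAs stood higher under the diet at 13 months and lower at 26 months (median interaction −0.65), with mt-Nd1, a subunit of complex I, at −0.66 ± 0.19, and 6 passed when adjusted over the list alone. All 17 myelin genes had a positive interaction (median 0.26, 1 when adjusted over the list alone), with Mag at 0.46 ± 0.13 and Mog at 0.38 ± 0.12. Excitatory neuron genes (median −0.21, 2 when adjusted over the list alone), synaptic genes (−0.14), cortex and hippocampus genes (−0.26) and meningeal genes (−0.26) had negative interactions.

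No gene of 17762 was called for an interaction by edgeR, DESeq2 or limma-voom, with 783, 630 and 767 at an unadjusted p below 0.05, where about 888 are expected by chance. The 5 smallest p belonged to Kcnk13, a potassium channel of microglia (0.78 ± 0.16), Lrch2 (−0.48 ± 0.11), Lgi3 (0.33 ± 0.08), Cnksr2, a synaptic scaffold (−0.36 ± 0.08), and Phldb1 (0.42 ± 0.10), all with an adjusted p of 1. The age effects on C4b (0.20 ± 0.17), Gfap (0.17 ± 0.18), Serpina3n (0.27 ± 0.23), Clec7a (−0.31 ± 0.59) and Cst7 (−0.38 ± 0.68) did not differ between diets by this test. Bdh1 (0.07 ± 0.11), Oxct1 (0.03 ± 0.08), Slc16a1 (0.04 ± 0.15), Pdk4 (−0.06 ± 0.28), Cpt1a (−0.02 ± 0.19), Fkbp5 (−0.23 ± 0.32), Nlrp3 (−0.14 ± 0.50) and Bdnf (−0.18 ± 0.16) did not pass. With a term for the low-18S libraries, chosen after seeing the data, 2 genes passed, Mag (0.48 ± 0.08) and mt-Tp (−0.77 ± 0.14), and without those libraries mt-Tp and mt-Nd6 (−0.48), the mitochondrial pair chosen after their values were seen. With that term, 13 genes passed without A, 9 without E, 26 without R, 1 without B, F, H, J or N, 2 without L and 0 without each of the others, and 1 surrogate variable gave 8. Over all libraries the term gave 1586 genes at an unadjusted p below 0.05.

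Of the 12 lists with an interaction by the preset correlation, those of mitochondrial mRNAs and of myelin, excitatory neuron, synaptic, meningeal and cortex genes kept the call with each library left out. The other 6 were blood cells (median 1.48), cerebellum (0.21), olfactory bulb (0.35), glycolysis (0.06), oxidative phosphorylation (0.06) and interferon response (−0.11). Blood cells lost the call without P (adjusted p = 0.0562), the cerebellum list without C (0.0873), J (0.373), M (0.0676) or P (0.103), and the olfactory bulb list without C (0.144), E (0.0573) or G (0.148). Interferon genes lost it without A (0.076), E (0.0517), K (0.36), L (0.184), P (0.0562) or R (0.175). Glycolysis lost it without B (0.0773), E (0.196), J (0.279), K (0.394), O (0.0587) or Q (0.167). Oxidative phosphorylation lost it without B (0.455), E (0.159), K (0.893), O (0.221) or P (0.252), and changed direction without J (0.839). The ketone body (adjusted p = 0.567) and PPAR target lists (0.384) had no interaction call.

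Across genes, the diet changes at 13 and 26 months had a Pearson r of −0.0171 (exact permutation p = 0.864 over 4900 regroupings), in comparisons that share no library. Whether the diet at 26 months moved genes such as C4b and Gfap back from their change with age was examined by correlating the age change in controls with the diet change at 26 months. These share the 26-month control libraries, and r was −0.396, against −0.486 in simulated groups without any effect. The covariance was −0.0179, against −0.0166 with an SD of 4.49e-04 over 20 simulations, a difference of −0.00134. With the shared libraries split 2 and 2, r was 0.184 (exact permutation p = 0.429 over 70 regroupings), against 0.213 with an SD of 0.0098 in simulated groups without an effect, whose values carry the same low-18S libraries. The split covariance was 0.0146, against 0.0137 with an SD of 6.17e-04 in simulations, a difference of 8.78e-04, opposite in sign to that of the unsplit covariance. With the low-18S term removed, the split r was −0.0378 (exact permutation p = 0.443), against −0.0236 with an SD of 0.0101 in simulations. Its covariance was then −0.00224, against −0.00116 with an SD of 5.02e-04, a difference of −0.00107, so the sign of the difference depended on the split and on the term. The simulations draw every gene independently. Their SDs leave out variation that genes share, so they cannot show whether these differences are large.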

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

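The splits of the libraries that recount genes and gene lists were planned, and the splits with a term for low 18S rRNA, those balanced for the low-18S libraries and the tests of the 3 patterns weighed here were chosen after the results were seen.

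The first pattern is the 4 libraries with little 18S rRNA, in which regions of transcription awaiting experimental evidence (TEC gene models) took 0.7005% of counts in C, 0.708% in J, 0.674% in K and 0.598% in R, each far from the rest of its group. With rRNA genes left out and scaling repeated, 38.4% of tested genes still differed. The first fit, also scaled by TMM, had 3566 genes higher and 3262 lower, so repeating the scaling was not a separate test. Differences left after scaling argue against fewer rRNA counts rescaling the rest as the whole cause. Genomic DNA would add CPM per kb alike to TEC models and to olfactory and vomeronasal receptor genes, and the smallest ratio between them over the 4 libraries was 127, which argues against DNA as the whole cause. Some DNA may be present. These receptor genes were at 31.3 to 37.2 CPM against 13.8 to 21.7 in the other 12. A few gene models taken as satellite repeats held 0.0139 ± 0.00954% of counts (SD, n = 4) against 2.61e-04%. Per kb, TEC models were at 0.917 to 1.08 CPM against 0.407 to 0.531, and receptor genes at 0.00609 to 0.00724 against 0.00268 to 0.00422. Both rose in similar proportion, so the receptor rise may share the source of the TEC rise and is not by itself a sign of DNA. Nuclear or unspliced RNA may be another source, since nuclear long noncoding RNAs had a median log2 difference of 0.56. No biological explanation was tested, as each group holds 1 such library.

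The second pattern is the olfactory bulb list, lower at 26 months in controls. With an estimated correlation and 1 library left out, its largest adjusted p was 0.038 (without K), which argues against 1 library as the whole cause. Less bulb tissue in the 26-month libraries may also lower it, and markers of mitral and tufted cells (log2 −1.19, exact permutation p = 0.0571) and of interneurons (−0.62, exact permutation p = 0.0286) were both lower. Both sets hold members of the list already called lower, such as Eomes and Pbx3, so their fall is not separate support. The difference between the sets could count against less tissue only if interneuron markers fell more. Mitral and tufted markers fell more (interneuron minus mitral and tufted 0.566, exact permutation p = 0.0571). Less tissue can therefore not be told apart from a change in bulb cells by this test. An effect of age itself stays open and untested. The bulb score also differed between diets at 26 months. It was −0.234 ± 0.0918 under the ketogenic and −0.502 ± 0.0902 under the control diet (SD, n = 4 per group), with no overlap. The difference of 0.268 had an exact permutation p of 0.0286, or 0.767 when adjusted over the lists. Camera did not call this list for the diet at 26 months. Whether bulb tissue or the diet lies behind this difference was not tested.

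The third pattern is the myelin list, called higher under the ketogenic diet at 26 months with the preset correlation, but not with an estimated one (adjusted p = 0.849) or by fry (0.855). Among the libraries outside the low-18S set, the score was higher by 0.145, at 0.252 ± 0.0134 against 0.107 ± 0.0446 (SD, n = 3 per group) with no overlap, which argues against the low-18S libraries as the whole cause. Over all libraries the difference was 0.221 (exact permutation p = 0.0571). More myelin-rich hindbrain tissue could raise it, and the hindbrain list differed by 0.392 with an exact permutation p of 0.629, so it cannot be told apart from the diet with these few libraries. An effect of the diet stays open, and chance is not excluded by the exact permutation p of the score.

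Splits into groups of the same sizes gave these counts. For age in controls, 1 of 35 splits, the real one with 37 genes, gave as many (highest other 5). For age under the ketogenic diet it was 1 of 35 (39 genes, highest other 0). Each is the smallest share that 35 splits can give, and is under 0.05. Some of the 35 put the low-18S libraries on 1 side, so chance is not excluded by them alone. With the low-18S term the count was also 1 of 35 each (143 genes, highest other 7, and 675 genes, highest other 2). In each of these 4 counts the real split was 1 of 20 with 1 low-18S library on each side (highest other 0 and 0, with the term 3 and 2), and 20 splits are too few for a share under 0.05. Every split reaches a count of 0, so the splits say nothing about the 0 genes of the diet at 13 months (35 of 35, highest other 1; with the term 35, highest other 5), at 26 months (35 of 35, highest other 0), averaged over ages (100 of 100; with the term 100, highest other 9) or of the interaction (100 of 100, highest other 1). For the averaged diet, the highest other count was 725 genes, in a split without 1 low-18S library in each group. Splits with these libraries balanced called at most 1. For the diet at 26 months with the term, 2 of 35 splits gave as many as the real 14 genes (highest other 26), so chance is not excluded. Of its 20 balanced splits, with 1 low-18S library on each side, 1, the real one, did so (highest other 6), and 20 splits are too few for a share under 0.05. For the interaction with the term, 13 of 100 splits gave at least 2 genes (highest other 17), and 12 of 39 balanced ones did, so chance is not excluded.

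For counts of gene lists, chance is not excluded over all splits, and many of these put the low-18S libraries on 1 side. For the 19 lists of age in controls, 11 of 35 splits gave as many (highest other 34), and 1 of the 20 balanced splits, the real one (highest other 18), which is too few splits for a share under 0.05. For the 23 lists under the ketogenic diet it was 6 of 35 (26) and 3 of 20 balanced (26). For the diet it was 20 of 35 (24) and 6 of 20 balanced (12) for the 9 lists at 13 months, 33 of 35 (26) and 18 of 20 balanced (15) for the 7 at 26 months and 83 of 100 (31) and 25 of 39 balanced (19) for the 6 averaged. For the 12 lists of the interaction it was 42 of 100 (26) and 9 of 39 balanced (16).

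A library far from the rest of its group was found in 19 of 124 groups of 4, where chance gives about 1 in 20, or 6.2. The excess cannot be read against chance. The measures include TEC, Malat1, Alb and S100a9, in which such libraries had been seen. They are also related to each other, and most flags fall on the low-18S libraries C, J, K and R. Malat1 took 1.11% of counts in K, against 0.511 to 0.533% in its group. Alb had 1912 counts in G, against 0 to 12. S100a9 had 161 counts in P, against 11 to 18, and 8 in A, against 1 to 2. Hbb-bs, a globin of red blood cells, had 4113 counts in C, against 568 to 1161. Clec7a was at 1.31 CPM in H, against 0.272 to 0.44. Oxct1 was at 183 CPM in F, against 167 to 169. Slc16a1 was at 34.8 CPM in J, against 43.9 to 45.1. Pdk4 was at 10.002 CPM in L, against 8.36 to 8.51. Fkbp5 was at 27.8 CPM in J, against 20.3 to 20.5. The disease-associated microglia score was −0.476 in J, against −0.339 to −0.317. The myelin score was −0.406 in J, against −0.0556 to −0.00361, and 0.107 in R, against 0.237 to 0.263. The olfactory bulb score was −0.367 in K, against −0.553 to −0.538. The cerebellum score was 0.365 in C, against −0.00287 to 0.0389.

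Lists whose diet effect differed between ages by the preset correlation were mitochondrial mRNAs (adjusted p = 5.54e-08), myelin (4.42e-06), synaptic genes (1.91e-04), excitatory neurons (6.76e-04), meningeal fibroblasts (8.43e-04), cortex and hippocampus (0.00151) and blood cells (0.00497). The others were the cerebellum (0.00959), glycolysis and olfactory bulb lists (0.0196 each), oxidative phosphorylation (0.0267) and interferon response (0.0293). With an estimated correlation the adjusted p of each was 0.883.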

How the results depend on the processing

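The settings with a term for low 18S rRNA, without the 4 low-18S libraries, with 1 library left out beside that term, with an estimated correlation and 1 library left out, and with a myelin covariate were chosen after seeing the data, and the other settings were planned. The gene counts for age stayed within 1.5 times of 37 and 39 with DESeq2 size factors (37 and 41), upper-quartile scaling (34 and 55), no low-count filter (43 and 39, which hold 29 of the 37 and 31 of the 39), a filter of 1 CPM in 4 libraries (40 and 48), limma-voom (27 and 27) and mitochondrial genes left out (40 and 38), and the diet and interaction counts stayed at 0 in these settings. Of the values of named genes under all alternatives, 3999 kept their side of the threshold, 96 passed newly, 148 no longer passed and 0 reversed (9 without an adjusted p from DESeq2 are left out), and for gene lists 1044 kept it, 324 no longer passed and 4 reversed. All libraries were male by Xist and Ddx3y, so the planned sex term was not run. No paired analysis was possible because the groups share no replicate label. At this depth and spread, simulated changes of 1.5-fold were recovered for 43 of 98 genes, so smaller diet effects can be missed. Except where a setting by construction uses fewer libraries or a stricter fold, the cause of each difference was not tested.

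DESeq2 called 81 and 160 genes for age in controls and under the ketogenic diet and 1 for the diet at 26 months. The compared groups alone gave 15 for age in controls. A test against a fold of 1.2 gave 6 and 15. With 1 surrogate variable, which separates the low-18S libraries, the age counts were 135 and 636, the diet at 26 months had 31, the interaction 8, and 12 lists were called for the diet at 26 months. A term for low 18S rRNA gave 143 and 675, 14 for the diet at 26 months, 2 for the interaction and 11 lists for the diet at 26 months. Without the 4 low-18S libraries these were 108, 547, 58 and 2, and the lists of the diet numbered 5 at 13 months, 14 at 26 months, 12 averaged and 7 for the interaction. With the term and G left out, age under the ketogenic diet had 490 genes and the averaged diet 1, Glra3 (−0.41). The averaged diet also had 1 gene with the term and N or Q left out, and the diet at 13 months 1 with F left out. With the term and P left out, age under the ketogenic diet had 312 genes and the diet at 26 months 8. With the term and a myelin covariate, the diet at 26 months had 2, Rgs5 (−0.67) and Lrch2 (−0.56), the first chosen after its values were seen, as was Glra3 here.

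Camera with an estimated correlation called 7 lists for age in controls, 4 under the ketogenic diet and 0 in the other comparisons, fry 9, 7 and 0, and an estimated correlation with the low-18S term 7, 5 and 0. The correlation of the age changes was 0.341 with the low-18S term removed, the same by construction, with an exact permutation p of 0.0049 in place of 0.186. Without J, the oxidative phosphorylation list reversed for age under the ketogenic diet (adjusted p = 0.41), the diet at 13 months (0.113) and the interaction (0.839), and the ribosomal list for the diet at 13 months (0.245). Over the libraries left out, the oxidative phosphorylation list ranged from 6.56e-05 (without G) to 0.41 for age under the ketogenic diet, from 1.57e-06 (without G) to 0.966 (without B) for the diet at 13 months and from 9.32e-05 (without G) to 0.893 (without K) for the interaction, and the ribosomal list for the diet at 13 months from 3.25e-08 (without G) to 0.513 (without B).

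With 1 library left out, age in controls had 8 (without L) to 42 genes (without K) and age under the ketogenic diet 16 (without P) to 74 (without R), while the diet and interaction counts stayed at 0. Lists numbered 7 (without P) to 15 (without K) for the diet at 26 months, with 12 without L or Q, 11 without M and 14 without R, and 6 (without N) to 15 (without J) for the averaged diet, with 11 without E, 10 without L or M and 12 without R. They stayed within 1.5 times in the other comparisons, at 16 to 23 for age in controls, 20 to 26 under the ketogenic diet, 7 to 10 for the diet at 13 months and 8 to 16 for the interaction.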

Other observations

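The test of the microglia and interferon scores was chosen after the result was seen, as were the olfactory bulb genes named here apart from those of the fixed rule.

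Several gene groups were not called in any of the 6 comparisons, even with the preset correlation. Senescence-associated genes (8 tested) had a median log2 change with age of 0.11 in controls (adjusted p = 0.178) and −0.02 under the ketogenic diet (0.857), and neurogenesis and proliferation genes (16) −0.02 (0.334) and 0.02 (0.857). Astrocyte markers had 0.02 (0.954) and 0.05 (0.192), beside the reactive astrocyte genes that rose. For the diet at 26 months, insulin, IGF and nutrient signalling genes had a median of 0.03 (adjusted p = 0.823), ATF4 targets 0.06 (0.158), the unfolded protein response 0.05 (0.253), heat shock genes −0.02 (0.725) and fatty acid synthesis genes 0.05 (0.158). In that comparison, glutamate and GABA metabolism had −0.01 (0.725), oligodendrocyte precursors 0.02 (0.205), endothelial cells 0.01 (0.584), ependymal cells −0.20 (0.126), collagens 0.03 (0.635), striatum −0.13 (0.0959), hindbrain 0.16 (0.253) and pituitary 0.09 (0.539).

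Among olfactory bulb genes with age in controls, Eomes (−2.07 ± 0.48 SE), Cdhr1 (−1.88 ± 0.47) and Doc2g (−1.90 ± 0.44), markers of mitral and tufted cells, and Sp8 (−1.67 ± 0.37), a transcription factor of bulb interneurons, did not pass by edgeR's quasi-likelihood test (adjusted p = 0.143, 0.246, 0.121 and 0.0971). Gng4 and Pbx3, both in the set of bulb interneuron markers, passed that test (adjusted p = 0.0115 each).

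At 26 months the disease-associated microglia list was higher and the interferon list lower under the ketogenic diet with the preset correlation, and neither was called with an estimated correlation (adjusted p = 0.849 each). The microglia call was also lost without K (adjusted p = 0.151) and the interferon call without the 4 low-18S libraries (0.359). A hypothesis, which rests on these calls, is that the diet may move the groups apart. The microglia score minus the interferon score was higher by 0.469 under the diet, with an exact permutation p of 0.0857 (n = 4 per group), so the hypothesis was neither excluded nor borne out.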
